A study of Mus musculus with 6 samples.

How the data were processed

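Gene expression was measured in macrophages grown from mouse bone marrow with recombinant human macrophage colony-stimulating factor at 50 ng/mL. On day 7 of culture 3 samples received bacterial lipopolysaccharide (LPS) at 10 ng/mL for 4 h and 3 stayed unstimulated. LPS is a component of the outer membrane of Gram-negative bacteria and the ligand of the receptor TLR4. Total RNA was labelled and hybridised to Affymetrix mouse exon arrays, with 1 array per sample and 6 arrays in all.

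The deposited values are log2 expression values made by the authors, with 1 value per transcript-level probe set and array, per the labels and the series text. The submitters' processing notes name PLIER, which summarises the probes of a set into 1 value, and Affymetrix Power Tools, without a version. The probe-set definition, its annotation release, the genome build, any offset before the logarithm and any normalization between arrays are not given in the sources used here. The 74007 rows carry Ensembl mouse transcript identifiers ending in _at. The columns have close but unequal quantiles, so the summarised values were not forced onto a single distribution. Whether probe values were normalized before they were summarised cannot be told from this. No detection call or background level was among the files used here, so a dim transcript cannot be told from an absent one.

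The rows could not be given gene names. The gene table at hand holds 49997 symbols and 0 Ensembl identifiers, and the files do not pair identifiers with symbols. The 40 gene lists that had been fixed for macrophage activation, metabolism and contaminating cell types were therefore not tested, and genomic positions are not given. The same holds for the list tests and for the settings that combine rows by gene symbol. The results are described by groups of transcripts (by direction, size of change and expression level), and 2 identifiers that rose and 2 that fell are printed. A gene with several transcripts can contribute several rows. Of the rows, 5192 shared all 6 values with at least 1 other row, which leaves 71258 distinct sets of values.

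Samples were grouped by their titles. The test was limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the log2 values as deposited, over all 74007 rows and both groups, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every difference is LPS minus unstimulated. With 4 residual degrees of freedom per row, eBayes added 2.58 prior degrees of freedom at a prior SD of 0.0857. No filter, offset or further normalization was applied. Calls of at least 2-fold also needed an absolute log2 difference of at least 1. The named-transcript rule took the 12 largest rises and the 12 largest falls among called rows with 1 sign in all same-numbered pairs and a mean in the higher group at or above the median row; the first 2 of each are printed. The model and most alternatives were fixed before the data were examined. The rule was fixed for gene symbols and passed over those that are only a clone or accession name. That clause was dropped to apply it to transcript identifiers, and printing 2 each way was not part of it.

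The series text says that each of 3 animals gave 1 culture to each group. Deviations of same-numbered arrays from their group means correlated at 0.50, 0.30 and 0.12 across transcripts, each above 0.1, so the numbers were taken to pair the arrays. LPS array 3 nevertheless correlated more closely with unstimulated array 2, at 0.21. The fit with the number as a block is an alternative.

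The script was tested on simulated data with the levels of this comparison and independent normal noise of the variances that eBayes gave. The simulation held no shift by level, no pairing and no rows sharing values, so its false calls do not cover these. Among 74007 transcripts, 200 were changed. A change of 0.5 on the log2 scale was recovered for 43.3% of the 67 transcripts given it. Changes of 1 and of 2 were recovered for 100% of the 67 and 66 transcripts given them, and 5.81% of all calls were false. With 24669 transcripts changed, 95.7% of the changes of 0.5 were recovered and 3.44% of calls were false. The number of arrays limits the precision. Alternatives covered the block, an offset of 16, quantile, median and cyclic loess normalization, centring on the transcripts above the median level, filters on dim rows, eBayes settings, distinct rows only, limma's treat, and each array left out in turn. Levels are described by 10 bins of equal size, with transcripts ranked on their mean over all 6 arrays. Signals of different probe sets also depend on their probes, so levels here are array signals and do not rank transcripts by abundance. The modal difference of a bin is the peak of a kernel density with a bandwidth of 0.05. For shares of signal, values were taken out of the logarithm and the 1st percentile of each array was subtracted as background. Figures were drawn with matplotlib 3.10.9.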

Results

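The data set comprised 6 exon arrays of bone marrow-derived macrophages from female C57BL/6J mice, 3 unstimulated and 3 exposed to LPS at 10 ng/mL for 4 h. Each array gave a log2 expression value for 74007 Ensembl transcripts. Values ran from 5.84 to 14.3 in unstimulated array 1 and over similar ranges in the other arrays. Transcripts are the units throughout, because the identifiers could not be matched to gene names. Their number per direction is thus not a number of genes.

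Arrays of the same group resembled each other more than arrays of different groups. Across transcripts, which are not independent replicates, Pearson's r lay between 0.986 and 0.993 for the 6 pairs within a group. It lay between 0.910 and 0.926 for the 9 pairs between groups. The first principal component held 85.0% of the variance and separated the 3 LPS arrays from the 3 unstimulated arrays. The second held 6.94% and placed array 1 of both groups at one end. The median SD of a transcript between arrays was 0.0782 in the unstimulated group and 0.0940 in the LPS group (n = 3 each).

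**Figure D1:**
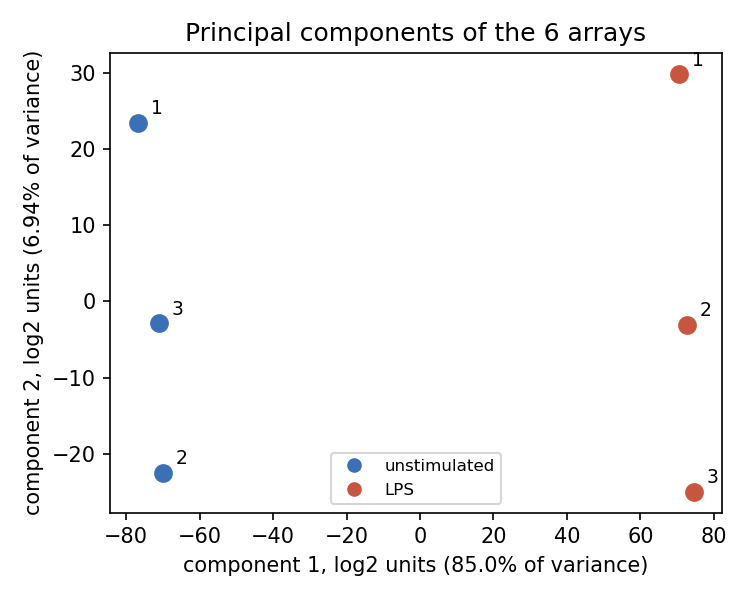
Principal components of the 6 arrays over all 74007 transcripts; the x axis is component 1 (85.0% of variance) and the y axis component 2 (6.94%), both in log2 units, and each point is an array with its replicate number. The 3 LPS arrays lie on the right and the 3 unstimulated arrays on the left.

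The comparison of LPS with unstimulated macrophages asks which transcripts respond to stimulation of TLR4. Expression changed for 23667 of the 74007 transcripts (32.0%), of which 6472 were higher and 17195 lower with LPS (limma, Benjamini-Hochberg adjusted p under 0.05). The balance depended on scaling: with each array centred on its median, 35595 transcripts were called, 23708 higher and 11887 lower. Most of the changes in the deposited values were small: 4250 transcripts were higher and 15012 lower by less than 2-fold. A change of at least 2-fold was found for 4405 transcripts, 2222 higher and 2183 lower. All 4405 had the same sign in each of the 3 same-numbered pairs of arrays, which their selection on these same arrays made likely. Within each pair the change was at least 2-fold for 1728 of the transcripts called higher and for 1401 of those called lower. With each array centred on the transcripts above the median level, 2776 were at least 2-fold higher and 1397 lower. After cyclic loess normalization the counts were 2680 and 1401. When the test asked whether the change exceeded 2-fold (limma's treat), 1072 transcripts passed as higher and 515 as lower.

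The largest changes were rises. Among transcripts that changed at least 4-fold, 661 were higher and 164 lower with LPS, so that 80.1% of them rose. At 16-fold or more the counts were 78 higher and 3 lower. The share that rose among changes of at least 4-fold lay between 78.5% and 87.0% under all 18 alternative settings for which it was computed. The highest value of 87.0% came from centring on the transcripts above the median level and the lowest of 78.5% from leaving out unstimulated array 2.

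The 2 largest rises were close in size. The log2 expression of ENSMUST00000043315_at was 6.35 ± 0.046 without and 12.5 ± 0.21 with LPS (SD, n = 3 each), a difference of 6.20 ± 0.11 (SE) or 73.4-fold (limma adjusted p = 1.33e-06). ENSMUST00000022722_at was at 7.34 ± 0.17 without and 13.5 ± 0.058 with LPS (SD, n = 3 each), a difference of 6.14 or 70.8-fold (limma adjusted p = 8.99e-07). The 2 differ by less than 1 SE, and their order turned with an offset of 16 and without unstimulated array 2 or LPS array 2. The 12 largest rises under the naming rule ranged from 40.6-fold to 73.4-fold. These 12 transcripts had unstimulated means between 6.13 and 7.34 and LPS means between 12.0 and 13.5. The lowest of these unstimulated means lie near the lower end of the scale, where absent transcripts cannot be told from dim ones, so these folds hold for the deposited scale and are lower bounds for any transcript that was absent.

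Among the largest falls was that of ENSMUST00000149663_at, from 11.9 ± 0.11 to 7.41 ± 0.10 (SD, n = 3 each), a difference of -4.47 ± 0.081 (SE) or 22.2-fold (limma adjusted p = 1.64e-06). ENSMUST00000074300_at fell from 11.8 ± 0.14 to 7.44 ± 0.065 (SD, n = 3 each), a difference of -4.40 or 21.2-fold (limma adjusted p = 1.66e-06). The latter shared all 6 values with 1 other row, so those 2 rows are a single measurement. The 2 printed falls were also close in each same-numbered pair. Their differences were -4.64, -4.23 and -4.54 for the first and -4.57, -4.19 and -4.45 for the second. They need not be separate measurements. The 12 largest falls ranged from 9.73-fold to 22.2-fold and held 11 distinct sets of values, some of them close to each other. Their unstimulated means lay between 10.7 and 11.9 and their LPS means between 7.21 and 7.89. Without a detection level these folds, too, hold for the deposited scale and are lower bounds for any transcript that was absent with LPS. The largest limma adjusted p among all transcripts named by the rule was 6.54e-05.

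**Figure D2:**
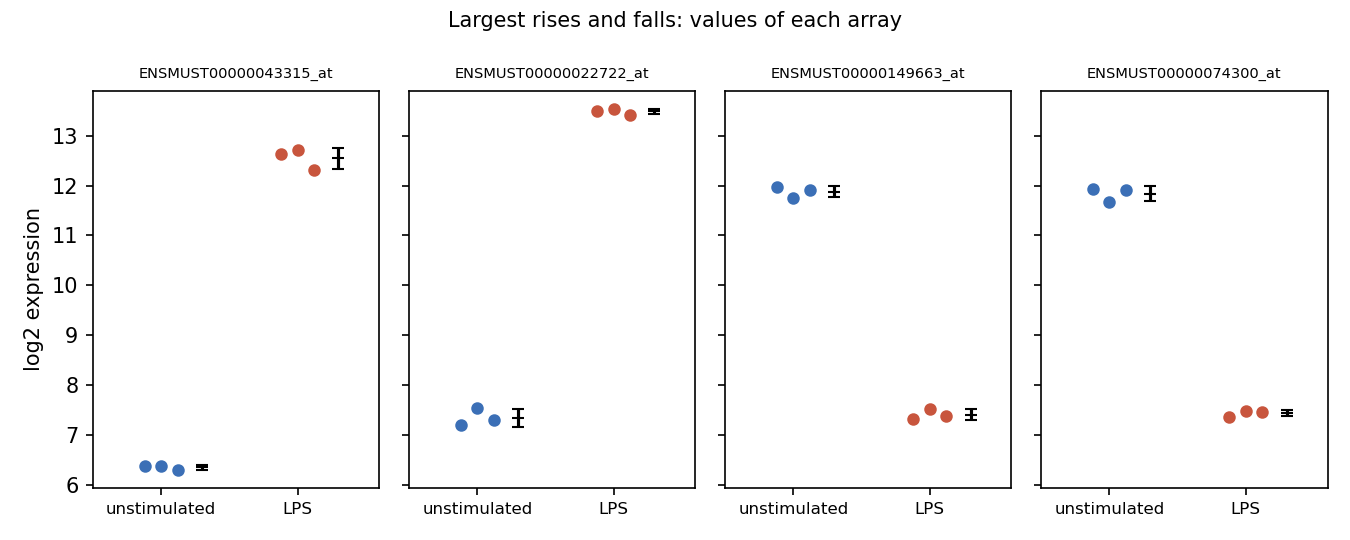
Log2 expression (y axis) of the 2 transcripts with the largest rises and the 2 with the largest falls; each point is an array, in the order of its replicate number, with the unstimulated group in blue and the LPS group in red, and the black bars give the mean and SD of 3 arrays. The groups do not overlap for any of the 4: for ENSMUST00000043315_at the means were 6.35 and 12.5, and for ENSMUST00000149663_at they were 11.9 and 7.41.

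The scale has a lower end near 6, so a dim transcript has little room to fall, and transcripts lowered at least 2-fold necessarily start above it. Signals also depend on the probes of each set, so the values below do not compare abundance. The 2222 transcripts raised at least 2-fold had a median unstimulated value of 8.74, with quartiles of 7.91 and 9.60, and a median of 10.6 with LPS. The 2183 lowered at least 2-fold had a median unstimulated value of 9.69, with quartiles of 9.12 and 10.3, and a median of 8.25 with LPS. Among the 25% of transcripts that were dimmest without LPS, 146 rose at least 2-fold and 0 of 18502 fell that far (limma; also 0 at an unadjusted p under 0.05). Among the brightest 25%, 835 rose and 1636 fell at least 2-fold. From below the overall lower quartile of 7.07 to above the upper quartile of 9.03, 82 called transcripts moved up with LPS. In the opposite direction 8 moved down. With an offset of 16 these counts were 41 and 1, since the offset lifts dim values above the lower quartile, and after cyclic loess normalization they were 103 and 3.

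The share of changed transcripts differed with the signal level. Transcripts were ranked by their mean and divided into 10 level bins of equal size. In bin 1, the dimmest, 1.31% were called, 47 higher and 50 lower. In bins 7 to 9, with mean log2 expression from 8.30 to 10.1, between 52.8% and 52.9% were called. In bin 7, where lower calls were most numerous, 3208 transcripts were lower and 705 higher. In bin 10, the brightest, 1696 were higher and 1734 lower, and 786 rose while 239 fell at least 2-fold.

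**Figure D3:**
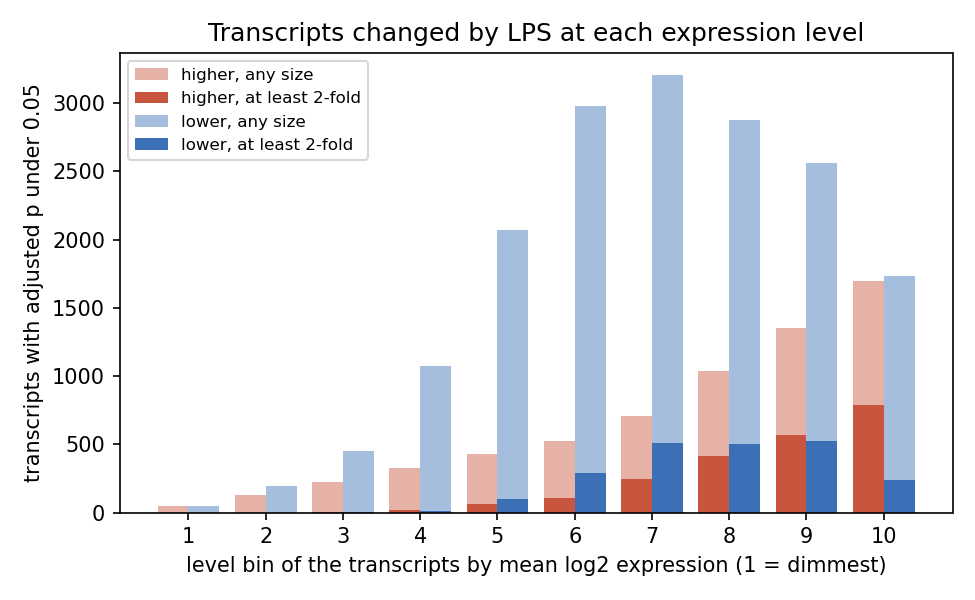
Number of transcripts with a limma adjusted p under 0.05 (y axis) in each of 10 level bins by mean log2 expression (x axis, 1 = dimmest); red bars are higher and blue bars lower with LPS, pale for any size and dark for at least 2-fold. Lower calls peak at 3208 in bin 7, and bin 10 holds 786 rises of at least 2-fold against 239 falls. The mean includes the LPS arrays, so a rise itself moves a transcript towards the brighter bins.

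The middle of the distribution was lower with LPS. The median over all transcripts was 7.92 ± 0.0088 in the unstimulated arrays and 7.77 ± 0.010 in the LPS arrays (SD, n = 3 each), a difference of -0.15. An exact permutation test that ignored the pairing gave p = 0.1 (two-sided), the smallest that 3 against 3 unpaired arrays allow. With the pairing kept, the smallest possible p would be larger. The median of the differences of single transcripts was closer to no change, at -0.022. The most frequent difference was near 0 in bins 1 to 6, at 0.021 in bin 1 and 0.024 in bin 6. It was -0.16 in bin 7, -0.23 in bin 8, -0.16 in bin 9 and -0.093 in bin 10. This peak hides falls in the middle bins. In bin 6 the median difference was already -0.18, with 2978 transcripts called lower and 524 higher. Without LPS array 3 the difference in bin 7 was -0.082 and that in bin 8 was -0.23, while that in bin 10 was larger, at -0.14. The balance of higher and lower calls of any size depends on how this shift is treated. Of all calls, 27.3% were higher in the values as deposited. That share was 43.4% after quantile normalization, 48.7% after cyclic loess normalization, 66.6% after centring each array on its median and 70.0% after centring on the transcripts above the median level. Of the 17195 transcripts called lower in the deposited values, 10999 were called lower after cyclic loess normalization and 10824 after centring on the transcripts above the median level.

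**Figure D4:**
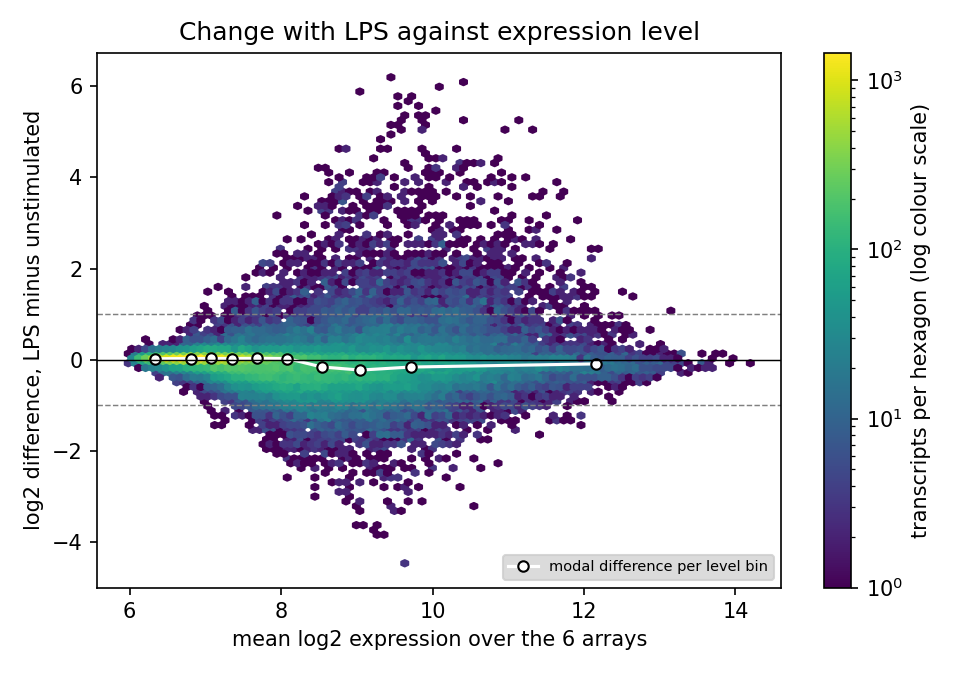
Log2 difference between LPS and unstimulated means (y axis) against mean log2 expression over the 6 arrays (x axis) for all 74007 transcripts; colour gives the number of transcripts per hexagon on a log scale, dashed lines mark 2-fold changes, and white points give the modal difference of each level bin. The modal difference stays near 0 up to bin 6 (0.024), where the median difference is -0.18, and reaches -0.23 in bin 8. The largest rises (6.20) exceed the largest falls (-4.47).

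The 3 same-numbered pairs of arrays showed similar differences. The log2 difference between LPS and unstimulated arrays was computed within each same-numbered pair, so that no array entered more than 1 difference. Across transcripts these differences correlated at 0.934 between pairs 1 and 2, at 0.910 between pairs 1 and 3 and at 0.895 between pairs 2 and 3. Their SDs over all transcripts were 0.551, 0.538 and 0.547. With the replicate number as a block, limma called 26284 transcripts, 7210 higher and 19074 lower, and 4411 at least 2-fold. Of the transcripts called without the block, 22813 were also called with it, as were all 4405 that changed at least 2-fold.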

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

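Cyclic loess normalization, centring on transcripts above the median level and the use of distinct rows only were added after the data had been seen. Across 343 comparisons of a result with an alternative setting, 320 stayed within the limits set for them, 21 moved and 2 reversed. The tally includes overlapping counts of the same calls. It also includes 18 alternatives for each of the 4 named transcripts, chosen for their large changes. It is therefore no measure of how stable the results are. The reversed result was the balance of all calls, of which 27.3% were higher as deposited, 66.6% with median centring and 70.0% with centring on transcripts above the median level. None of the 4 named transcripts lost its call or changed sign in any of 18 alternatives, though the order of the 2 largest rises turned in 3 of them. Counts moved by more than 1.5 times only with the scaling of the arrays, an offset or limma's treat. Changed transcripts numbered 23667 as deposited, 35595 with median centring (a shift of 0.15 for every transcript) and 36029 with centring on transcripts above the median level (a shift of 0.18), which add that shift to dim transcripts whose modal difference was near 0 before. Higher calls went from 6472 to 9768 with quantile normalization, 10499 with cyclic loess, 23708 with median centring and 25204 with centring on transcripts above the median level. Lower calls went from 17195 to 11053 with cyclic loess and 10825 with centring on transcripts above the median level. Transcripts changed at least 2-fold fell from 4405 to 1587 with treat, which tests against 2-fold itself, and lay between 4081 and 4411 under the other settings that kept all arrays. Leaving out any 1 array gave between 18380 and 22009 calls and between 4317 and 4557 of at least 2-fold. The replicate block (26284 calls) changed no count by more than 1.5 times. The offset of 16 cut the transcripts moving from dim to bright from 82 to 41. The 40 gene lists and the settings by gene symbol were not run for want of gene names. Only 1.31% of the dimmest level bin was called, where no detection level is known.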

Other observations

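The tests of splits, of a single shared shift, of the medians and of transcripts above the window were chosen after the results they bear on were seen; the other tests below were written before their results, though after the patterns they address.

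No transcript differed between replicate numbers at an adjusted p under 0.05 in limma's blocked fit, and 9996 did at an unadjusted p under 0.05. The lack of calls does not show that the pairs were alike. With the number as a random effect, limma estimated a correlation of 0.277 within pairs and called 27508 transcripts for LPS. The 6 arrays can be divided into 3 and 3 in 10 ways, and 1 of the 10 splits, the real one, gave as many calls. The highest other split gave 0 calls against 23667, with 471 to 3430 transcripts at an unadjusted p under 0.05 against 29403. For higher, lower and at least 2-fold calls the highest other count was likewise 0, against 6472, 17195 and 4405. Of the 4 splits that part all 3 pairs the others also gave 0. Each other split holds arrays of both groups on each side, so the LPS difference adds to its residual variance. Few calls are then certain in advance, and these counts are not a null expectation for the real split. With 10 splits no share under 0.05 can be reached.

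The first pattern is the lower level of mid-level and bright transcripts with LPS, with a modal difference of -0.23 in level bin 8. After centring on the transcripts above the median level, 62.9% of the lower calls were still called lower. That centring moved each difference by 0.18, while the median lower call was -0.52, so many calls were bound to stay lower. The 62.9% thus cannot decide whether a single shared shift was the whole source of the lower calls. A shift of 0.18 alone does not account for the 2183 transcripts lowered at least 2-fold. Induced transcripts taking a larger share of the labelled target stay open: among 71258 distinct sets of values, the 2138 raised at least 2-fold went from 3.20%, 3.43% and 3.47% of the linear signal of the unstimulated arrays to 14.2%, 14.1% and 13.4% of that of the LPS arrays, after subtraction of the 1st percentile of each array as background, and the 2110 lowered at least 2-fold went from 6.85%, 6.13% and 6.36% to 2.30%, 2.15% and 2.04%. The share left for the rest changed by a log2 ratio of -0.17 on average with the raised transcripts left out (-0.14 without subtraction) and of -0.10 with the lowered ones left out too, against a mean of -0.18 over the 3 level bins with the largest modal falls; the -0.14 and -0.10 were added later, and means over transcripts chosen in 1 pair of arrays and measured in the others were -0.17 and -0.10. The choice of transcripts that rose fixes the sign of the first value, and neither reaches the size set in advance. This explanation and a real fall of many mid-level and bright transcripts thus cannot be told apart without an external standard.

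The second pattern is the lower median of the LPS arrays, which drift between single arrays could produce. The medians differed by -0.15 between groups, while 2 arrays of a group differed by at most 0.019, which argues against such drift as the source of the lower median. In bins 7, 8 and 9 the modal difference was negative in all 9 pairs between groups. In bin 10 it was 0.078 between unstimulated array 1 and LPS array 3 and negative in the other pairs between groups. For the size of the modal shift by level, drift stays open, because 2 LPS arrays differed by up to 0.136 in bin 10 (without LPS array 3 the largest difference within a group was 0.0569). A technical difference shared by all 3 LPS arrays cannot be told from the effect of LPS in this design.

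The third pattern is the excess of rises among changes of at least 4-fold, for which the lower limit of the scale was tested, since it leaves dim transcripts no room to fall. Across the 4 groups of 25% by unstimulated signal, from dim to bright, 90, 188, 257 and 126 transcripts rose and 0, 0, 2 and 162 fell at least 4-fold. Inside the brightest group lay the 9197 transcripts whose unstimulated mean (9.24 to 10.1) was at least 3 log2 units from both ends. Of these, 99 rose and 45 fell, so that 68.8% rose (95% exact binomial interval 60.5% to 76.2%, too narrow where transcripts share probes). This interval met the rule set in advance for an excess without the scale limit. In the upper part of the window, split off later, the interval began at 50.4% (40 rose and 23 fell). The lower end was taken as 6.24 for all transcripts, however, and not as the background of each probe set. With LPS, the means of the transcripts that fell lay between 6.82 and 7.93. A transcript in the window may thus have less room to fall than 3 log2 units, and the test cannot decide on the scale limit. Between 10.1 and 11.1, where falls have more room, 18 rose and 85 fell (17.5% rose), which goes with the scale limit, but less room to rise could lower that share as well. Inside the window and outside it, the limit thus stays a possible source of the excess.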
